A study of Homo sapiens with 2 samples.

How the data were processed

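DEK ChIP-seq libraries of 786-O cells, 2 replicates of 1 group labelled as negative control with a wild-type genotype, were analysed from the authors' deposited peak lists, 1 list per library. Per the labels' protocols, chromatin was precipitated with a sonication-based kit and libraries were made with a commercial Illumina kit. Per the submitters' processing notes, the genome build was GRCh38 (hg38) and the tools used were cutadapt 1.18, Bowtie2 2.2.5, MACS2 2.2.7.1, DiffBind 3.6.5, ChIPseeker 1.32.1 and deepTools 3.5.1, which the notes list without roles. The peak lists were deposited separately for each replicate, and the peak names carry 1 library each, so replicates were called separately. Whether a control library was used in calling is not given in the sources used here.

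The deposited score of each peak was 10 times its −log10 q cut to a whole number in 100% of the peaks of replicate 1 and 99.95% of those of replicate 2. The fold enrichment deposited by the authors is a linear ratio at the summit within 1 library, and their −log10 p and −log10 q values belong to the same position. The smallest deposited −log10 q was 1.309 in replicate 1 and 1.303 in replicate 2, just above that of a q of 0.05. The last deposited column, an offset, gives the summit position in bp from the peak start. Fold enrichment is the authors' own value for each peak and was used here to describe, rank and filter peaks within a list and to set the replicates of 1 region side by side.

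The summit pileup was recovered by solving the fold enrichment, taken as (pileup + 1) over (background + 1), together with the Poisson p for a whole-number pileup. A whole number met the deposited p within a relative tolerance of 5e-05 in 100% of the peaks of both libraries. The background values then were whole reads per 10 kb in 100% of the peaks with a pileup under 100, within 0.05 reads, apart from peaks at the lowest background. This lowest background equalled 108 reads per 10 kb in replicate 1 and 128 in replicate 2, and 740 and 1402 peaks had it. With an assumed effective genome size of 2.7 Gb it corresponds to 29.3 M and 34.6 M reads, and other genome sizes would scale these depths. Background values in whole reads are what calling without a control library would give, and the text reads them as the library's own reads on that assumption, which the sources used here do not state. The median peak held 219 and 246 reads within 10 kb. With a median pileup of 19, the fold enrichment of a single peak has a wide counting error, and intervals given for shares cover counting error only.

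Peaks on chromosomes 1 to 22 and X were analysed, which left out 0.591% of the peaks of replicate 1 and 0.5% of those of replicate 2. Peaks of the 2 replicates that overlapped by at least 1 bp were joined into shared regions, and each region took the fold enrichment of its strongest peak per library and, as its summit, the midpoint of these peaks' summits. Random placement kept each region's width and chromosome and was drawn 1000 times with a fixed seed, so the smallest two-sided permutation p is 0.002. A second placement, chosen after seeing the data, moved each region by 50 to 500 kb. Regions per Mb were compared with 1000 draws over the chromosomes' spans, and correlations over chromosomes were tested with 100000 permutations. Fisher's exact test, two-sided, compared each of 25 gene lists with all other protein-coding genes, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Odds ratios are conditional estimates with exact 95% intervals, and shares have 95% Wilson intervals. The odds ratio and the percent difference replaced a log2 odds with a pseudocount after the output was seen, because that measure could take the opposite sign to the percentages in small lists, and the tests did not change.

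Gene names and positions came from a RefSeq gene table of GRCh38.p14, which has 1 row per gene and no strand, transcripts or sequence. The planned promoter around a stranded transcription start was therefore replaced, before any gene-list result was seen, by the windows within 1 kb of both annotated ends of a gene. The order of classes for a summit was gene end, inside a protein-coding gene, long non-coding RNA gene, pseudogene, stretch of at least 1 Mb without a gene, and other. The planned motif search, GC and CpG content, exon, intron and UTR classes, and the exclusion of assembly gaps needed a genome sequence or transcripts and were not run.

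A gene with several shared regions at its ends, or inside it where none lay at an end, is given the values of the region with the highest mean percentile of fold enrichment. The named genes followed a rule fixed before the data were examined: the 20 protein-coding genes with the highest mean percentile of fold enrichment among the shared regions at a gene end, the 4 highest members of each list that passed and the 2 highest of each other list, 15 fixed genes, the 10 highest regions and the 5 densest 1 Mb windows. The alternatives tried were −log10 q of at least 5, fold enrichment of at least 5, the 5000 peaks of lowest p, 50% reciprocal overlap, summits within 100 bp, each replicate left out, windows of 3 kb, removal of the 1% of regions with the highest fold enrichment, and a background without olfactory receptor and ZNF genes. Chosen after seeing the data were the local placement, an exact test within 10 strata of region density within 1 Mb, whole genes in place of gene ends, each region counted for its nearest gene alone, and removal of gene-free stretches and mitochondrial pseudogenes.

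On simulated data, 100% of 5000 pileups were recovered exactly. In the overlap test, 1 of 40 random lists was called at 0.05, and 20 of 20 lists with 5% of their regions kept in place were called. In the gene-list test on 19974 genes, 0% of unchanged lists were called. Of lists planted at 2-fold and 3-fold occupancy, 25.6% and 66.9% were called, so lists that did not pass can still differ. These simulations drew the occupancy of each gene independently. In the data neighbouring genes can share a region, so the 0% was not established for lists of clustered genes. Results for 1 of the gene lists and for certain genes that the rule names are not reported here. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.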

Results

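Chromatin bound by DEK, an abundant nuclear protein that associates with chromatin and histones, was profiled by ChIP-seq in 786-O cells, an established human renal carcinoma line. Both samples were labelled as negative controls of a Cas9 experiment with a wild-type genotype, and the antibody entry of both names DEK. The labels do not say whether negative control refers to the cells or to the precipitation. They were read here as 2 replicates of 1 group of control cells precipitated with a DEK antibody, and the regions are called DEK regions on that reading. No DEK-edited, input or other-antibody sample was analysed here, and the comparisons below are therefore between the replicates, against chance, and between genes. Replicate 1 had 19128 peaks and replicate 2 had 24580, of which 19015 and 24457 lay on chromosomes 1 to 22 and X. The peaks covered 6.26 Mb and 8.03 Mb, with median widths of 284 bp and 276 bp. The authors' fold enrichment at the summit had a median of 3.99 in replicate 1 and 3.89 in replicate 2, and only 134 and 157 peaks reached 10-fold. The sources used here do not say whether peak calling used a control library. The background values were whole reads per 10 kb, as calling without one would give. Fold enrichment may then be relative to the surroundings in the same library and not to an input. The summit pileup, the number of overlapping fragments solved from the authors' fold enrichment and p, had a median of 19 in both libraries and ranged from 9 to 333 and from 9 to 316, so a typical peak rested on few fragments. The labels do not say that the replicates came from separate cultures, and the spread between them may be technical.

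The first comparison asked how far the DEK peaks of the 2 replicates coincided. Overlapping peaks formed 12590 regions shared by both replicates, which held 12891 peaks of replicate 1 (67.8%) and 12773 peaks of replicate 2 (52.2%). The strongest shared region lay on chromosome 17 at 22521269 to 22521577, 711 bp from the mitochondrial pseudogene MTCYBP13, with a fold enrichment of 34.6 ± 0.136 (SD, n = 2). The highest-ranked shared region inside the renal lineage gene PAX8, which held 5 peaks of replicate 1 and 8 of replicate 2, reached 5.37 ± 0.601, and that inside the hypoxia-inducible factor gene EPAS1, which held 3 and 4, reached 4.77 ± 0.441 (SD, n = 2). Sharing rose with the strength of the peak: among the 25% of peaks with the lowest −log10 q, 46.6% of the peaks of replicate 1 (95% Wilson interval 45.2 to 48.0) and 27.2% of those of replicate 2 (26.1 to 28.3) were shared, and among the 25% with the highest −log10 q 92.4% (91.6 to 93.1) and 84.4% (83.4 to 85.3). Random placement of the replicate 1 peaks on their own chromosomes gave 121 ± 11 overlapping peaks (mean ± SD of 1000 placements), 106-fold fewer than the 12891 observed (two-sided permutation p = 0.002, the smallest the placements can give). When each peak was moved by 50 to 500 kb only, chance overlap was 218 ± 14.3 peaks and the excess was 59.2-fold (permutation p = 0.002, again the smallest possible).

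Across the shared regions the fold enrichment of the replicates correlated with a Spearman coefficient of 0.621 and a Pearson coefficient of 0.753 on the log2 scale, and the summit pileup with a Spearman coefficient of 0.813. These coefficients are across regions, which are not independent replicates, and no p is given. The median absolute log2 ratio of the fold enrichment between replicates was 0.17. Background values were solved from the authors' fold enrichment and p. On the assumption of calling without a control, they were read as the same library's reads within 10 kb of the summit. Between the libraries they scattered slightly more than counting noise (chi-square per degree of freedom 1.12 over 12040 regions).

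**Figure D1:**
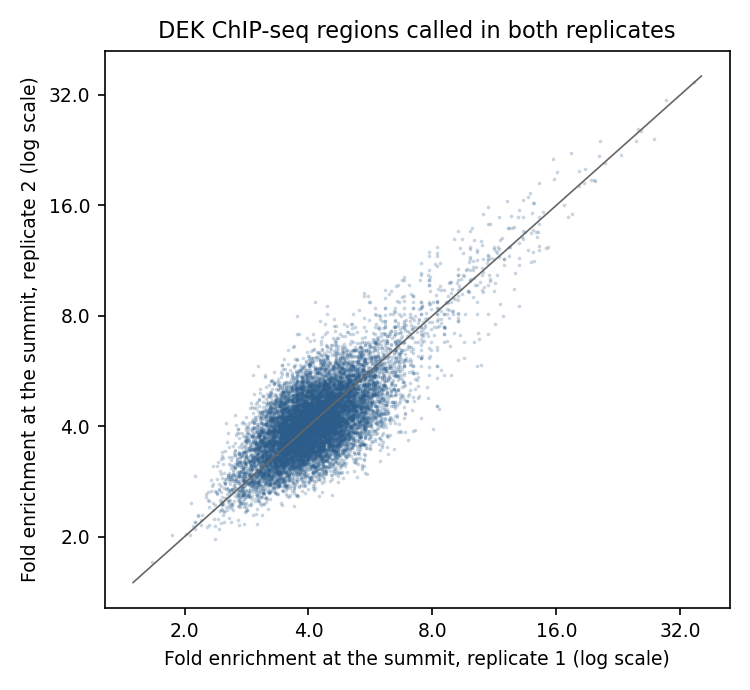
Fold enrichment at the summit in replicate 1 (x axis) and replicate 2 (y axis), both on log scales, for each of the 12590 DEK regions called in both replicates; the line marks equal values. The points spread around the line with a Spearman coefficient of 0.621, and the region of highest mean, on chromosome 17, lies at 34.5 and 34.7.

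The second comparison asked where the shared DEK regions lay relative to genes. Summits within 1 kb of either annotated end of a protein-coding gene made up 8.66% of the shared regions (95% Wilson interval 8.18 to 9.16), against 2.82% ± 0.141 (SD) in random placement, a 3.07-fold excess. A further 52.2% (51.3 to 53.02) lay elsewhere inside protein-coding genes, against 41.9% by chance. Long non-coding RNA genes held 8.59% against 11.5%, pseudogenes 0.969% against 1.43%, stretches of at least 1 Mb without a gene 4.71% against 5.88%, and the remaining intergenic sequence 24.9% against 36.5%. All 6 classes differed from chance on the same chromosome (two-sided permutation p = 0.002 each, the smallest 1000 placements can give). Assembly gaps were not kept out of the placements, so each chance share can include sequence in which no peak could be called. Gene-free stretches of 15.5 Mb on chromosome 14 and 15.3 Mb on chromosome 15 held 0 shared regions. The low share of the gene-free class cannot be told apart from an effect of gaps. With placement 50 to 500 kb from each region, the gene-end excess was 2.03-fold over a chance share of 4.27% and that inside protein-coding genes 1.05-fold. With that placement the share in gene-free stretches turned from below to above chance (1.06-fold over 4.44%), and the classes of long non-coding RNA genes (0.905-fold), pseudogenes (0.610-fold) and other sequence (0.810-fold) stayed below it. The gene table used here has no strand, so the end at which transcription starts was not separated from the other end.

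A shared region lay within 1 kb of an end of 1504 of 19974 protein-coding genes (7.53%, 95% Wilson interval 7.17 to 7.90). Taking only the highest-ranked region of each gene, these genes rested on 1237 distinct regions, because neighbouring genes can lie at the same region. The highest-ranked genes included BABAM1, which encodes a member of the BRCA1-A complex (chromosome 19, region 17266919 to 17267547, fold enrichment 7.65 ± 0.413), MPND (chromosome 19, 4342681 to 4343230, 7.58 ± 0.726) and PWWP2A, which encodes a chromatin protein that binds the histone variant H2A.Z (chromosome 5, 160119491 to 160119987, 7.32 ± 0.312; SD, n = 2 for each). The gene LOC102724652 on chromosome 21 had the highest mean percentile, at 7.83 ± 0.206. Other genes among the 20 highest were the translation elongation factor EEF1A1 at 6.33 ± 0.567 and JARID2, a cofactor of the polycomb complex PRC2, at 6.25 ± 0.431. The pair PPL and UBN1, which encodes a subunit of the HIRA histone chaperone complex, shared a region of 6.27 ± 0.318, and the pair DRC3 and TOM1L2 shared 1 of 6.45 ± 0.125. The 20 also held SYCE1L, KLRC2, MCC, LOC124900576, HDGFL2, MPV17L2, the pair ATG2A and PPP2R5B, and CCDC200. At ATG2A and PPP2R5B the replicates differed most, 5.57 in replicate 1 and 9.04 in replicate 2. Taking any peak of 1 replicate alone in place of shared regions raised the gene count to 2180 for replicate 1 and 2703 for replicate 2, and keeping only peaks of at least 5-fold lowered it to 121.

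The genes fixed in advance for this cell line fell into 3 sets. VEGFA, the angiogenic HIF target, had a shared region at its end of lower coordinate (chromosome 6, 43769492 to 43769896) with a fold enrichment of 3.399 ± 0.122. The glucose transporter gene SLC2A1 had 3.01 ± 0.0355, the cyclin D1 gene CCND1 3.03 ± 0.0047, MYC 3.89 ± 0.559 and the histone methyltransferase gene SETD2 3.43 ± 0.232 at an end (SD, n = 2 for each). DEK itself had no region at an end and a shared region inside the gene (chromosome 6, 18260512 to 18261003) of 3.93 ± 0.593, and EPAS1, PBRM1 (5.40 ± 0.309) and PAX8 likewise had regions inside the gene only. VHL, HIF1A, CA9, CDKN1A and BAP1 had no peak in either library at their ends or inside the gene. A missing peak means that none passed the authors' threshold at this depth, not that DEK was absent. VEGFA, SLC2A1, CCND1, MYC and SETD2 all lost the shared region at their ends when −log10 q of at least 5 was required.

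The third comparison asked which of 25 gene lists, fixed before the data were examined, had shared DEK regions at their ends more or less often than other protein-coding genes. Clustered replication-dependent histone genes had the highest share when a region could count for several genes, 21 of 69 (30.4% against 7.45% of other genes), led by the neighbours H2AC11 and H2BC11 (5.41 ± 0.763) and H2AC8 and H2BC8 (4.59 ± 0.344; SD, n = 2 for each). Genes of cytosolic ribosomal proteins had 21 of 81 (25.9%), among them RPL17 (4.88 ± 0.213), RPL41 (4.74 ± 0.349), RPL27A (4.77 ± 0.666) and RPL34 (4.64 ± 0.723). These are the 4 highest of the 21, whose median percentile of fold enrichment among the shared regions was only 29.1. That median was 10.1 for the hypoxia list and from 48.6 to 62.3 for the other lists that passed with a higher share. The ATF4 and unfolded protein response list had 8 of 30 (26.7%), with HYOU1 (4.33 ± 0.226), SLC7A5, CALR and SLC7A11, and the heat shock and chaperone list 8 of 31 (25.8%), with HSPA1B (5.08 ± 0.234), STIP1 (5.02 ± 0.283), HSF1 and CCT3. G2/M cell cycle genes had 13 of 54 (24.1%), with UBE2C (4.86 ± 0.0216), HMGB2 (4.83 ± 0.204), ANP32E and TOP2A. Olfactory receptor genes, which the plan took as not used outside olfactory tissue, had the lowest share, 2 of 390 (0.513% against 7.67%), OR2T1 and OR2V2.

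By Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 25 lists, the histone genes had an odds ratio of 5.43 (95% interval 3.08 to 9.28, p = 1.8e-08, adjusted p = 2.3e-07) and the ribosomal proteins 4.34 (2.50 to 7.27, p = 3.8e-07, adjusted p = 3.2e-06). The odds ratio was 3.92 (1.92 to 7.48) for G2/M genes (Fisher's exact p = 0.000142, adjusted p = 0.000887), 4.48 (1.72 to 10.5) for the ATF4 list (p = 0.00132, adjusted p = 0.00662) and 4.29 (1.66 to 9.95) for the heat shock list (p = 0.00167, adjusted p = 0.00696). Ribosome biogenesis genes, 9 of 41 with IMP4, NOLC1, BOP1 and RRP12, had 3.47 (1.45 to 7.45; exact p = 0.00294, adjusted p = 0.0105). Hypoxia and HIF target genes, 7 of 36 with ENO2, LDHA, VEGFA and DDIT4, had 2.97 (1.10 to 6.95; exact p = 0.0164, adjusted p = 0.0454), and core splicing factors, 9 of 52 with SF3B6, SF3B5, SNRPD2 and SNRPA, had 2.58 (1.10 to 5.38; exact p = 0.0147, adjusted p = 0.0454). The olfactory receptors had 0.0621 (0.0075 to 0.226; exact p = 4.3e-11, adjusted p = 1.1e-09). When −log10 q of at least 5 was required, the histone (adjusted p = 1.6e-07), splicing (0.0278) and olfactory receptor (0.0036) lists passed the exact test and the other 6 did not. No member of the hypoxia list then had a region (0 of 36, with 1.02 expected from the share of other genes; adjusted p = 0.792 by the exact test). The same held with a fold enrichment of at least 5 (0.218 expected) and with the 5000 peaks of lowest p (0.580 expected), too few to give a direction. None of the 9 passed with a fold enrichment of at least 5 or with the 5000 peaks of lowest p, where 121 and 321 genes were left. Stricter matching of the replicates kept 4 with 50% reciprocal overlap and 4 with summits within 100 bp. The hypoxia and splicing calls lay close to the threshold and also ended without replicate 1 (exact test, adjusted p = 0.108 and 0.0536) and with a background without olfactory receptor and ZNF genes (0.0525 for both). Windows of 3 kb raised the difference of the hypoxia list from other genes from 11.9 to 33.5 percentage points (adjusted p = 1.7e-05), while the G2/M (0.0515), splicing (0.0534), ribosome biogenesis (0.0534) and heat shock (0.124) lists no longer passed the exact test. The 21 histone genes rested on 10 distinct regions, taking only the highest-ranked region of each gene. With each region counted for its nearest gene alone, the difference of the histone list fell from 22.98 to 8.33 points (odds ratio 2.58, 1.17 to 5.11, exact test, adjusted p = 0.0401). It then lay below that of the ATF4 (20.5), heat shock (19.6), G2/M (16.1) and ribosomal protein (13.6) lists. Windows of 3 kb put it at 19.6, below the hypoxia and immediate-early lists, so the first rank of the histone list depended on these choices. The same count gave 10.5 points in place of 11.9 for hypoxia (odds ratio 3.04, 1.03 to 7.45; exact test, adjusted p = 0.0782). It gave 7.29 in place of 9.80 for splicing (2.37, 0.898 to 5.30; adjusted p = 0.111 by the exact test) and 8.46 in place of 14.5 for ribosome biogenesis (2.61, 0.894 to 6.28; adjusted p = 0.111), and these lists no longer passed.

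The other 16 lists did not pass in this test. Some passed under an alternative: oxidative phosphorylation when either replicate was left out (adjusted p = 0.0321 and 0.00991), histone chaperones (0.0165) and genes mutated in clear cell renal carcinoma (0.0355) without replicate 1, and immediate-early genes with windows of 3 kb (adjusted p = 0.000775 by the exact test). Histone chaperones and histone H3.3 genes had 6 of 30 (adjusted p = 0.056), with UBN1 and ASF1B, and oxidative phosphorylation subunits 11 of 74 (adjusted p = 0.0571 by Fisher's exact test), with NDUFA11 and ATP5MC1. Genes mutated in clear cell renal carcinoma had 3 of 20, with ELOC and MTOR, mesenchymal and matrix genes 5 of 36, with ITGAV and LOXL2, and G1/S genes 6 of 45, with CASP8AP2 and SLBP. The NF-kB list, with CCL20 and TNFAIP2, and the renal tubule list, with MIOX and KRT8, each had 4 of 32, and immediate-early genes, with KLF6 and MYC, 4 of 40. VHL-HIF pathway components had 1 of 17 (ELOC), double-strand break repair genes 3 of 40 (MDC1, FANCG and BRCA1), interferon-stimulated genes 1 of 36 (IFITM3), HOX genes 1 of 39 (HOXA5) and ZNF genes 34 of 509, with ZNF587 and ZNF564. Of the markers of cell types not in the culture, immune genes had 1 of 28 (CD68) and neuron genes 2 of 27 (SYT1 and NEUROD2). When the whole gene was tested in place of its ends, 4 of the 25 lists passed the same exact test: hypoxia and mesenchymal genes (adjusted p = 0.0481 for both) higher, ZNF genes (adjusted p = 5.9e-05) and olfactory receptors (adjusted p = 2.8e-36) lower. The calls of 7 of the 9 lists ended, and ribosomal protein, splicing, G2/M and ribosome biogenesis genes turned below other genes. Longer genes have more room for a region, and gene length was not adjusted for.

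**Figure D2:**
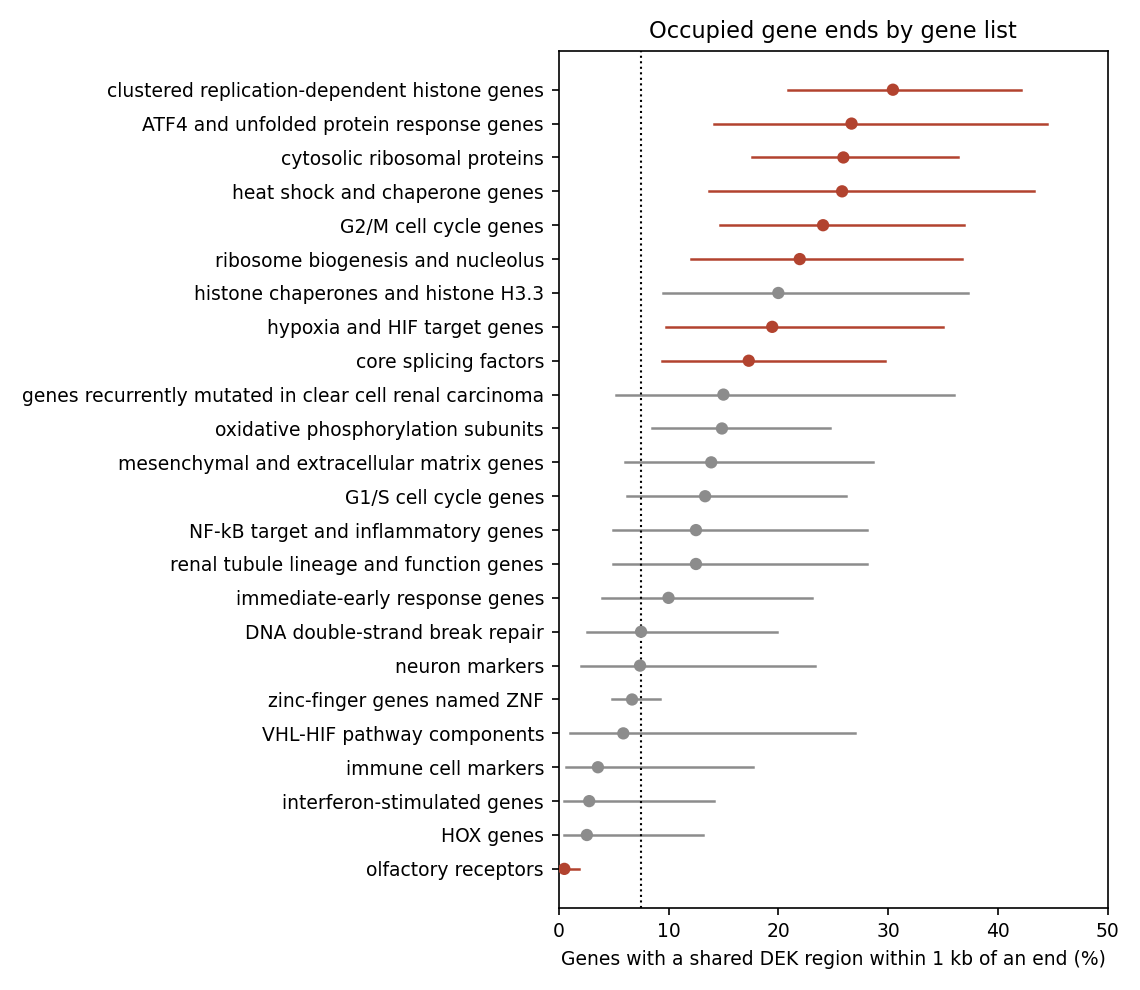
Percent of the genes of 24 of the 25 lists with a shared DEK region within 1 kb of an end (points) with 95% Wilson intervals (lines); red marks the 9 lists with an adjusted p under 0.05 by Fisher's exact test, and the dotted line marks 7.53%, the share of all protein-coding genes. Histone genes lie highest at 30.4% and olfactory receptors lowest at 0.513%.

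Genes of small nuclear RNAs had a shared region within 1 kb of an end in 35 of 154 cases (22.7%, 95% Wilson interval 16.8 to 29.96). These included RNU1-1, RNU1-2, RNU1-3, RNU1-4, RNU2-1, RNU4-1, RNU4-2, RNU5A-1 and RNU7-1, while the 5 RNU6 genes had none. Entries without a family name were also among the 35, with an unbroken run from LOC124904135 to LOC124904146. Entries that may be repeated copies at 1 locus were not set apart. The 45S ribosomal RNA precursor and its products had 9 of 16, all at the copies RNA45SN1, RNA45SN2 and RNA45SN3 and their 18S and 28S parts. Transfer RNA genes had 31 of 443 (6.998%, 4.97 to 9.76), long non-coding RNA genes 767 of 18177 (4.22%, 3.94 to 4.52) and pseudogenes 173 of 15212 (1.14%, 0.981 to 1.32). Taking only the highest-ranked region of each gene, the 31 transfer RNA genes rested on 23 distinct regions. The 9 entries of the 45S class rested on 6, and the 35 small nuclear RNA genes on 34. The intervals count genes at the same region as separate. Small nuclear and ribosomal RNA genes occur in near-identical copies among which reads cannot be placed with certainty. No test was planned between these classes.

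The fourth comparison asked how the shared DEK regions were spread over the chromosomes. Chromosome 19 carried 10.4 regions per Mb and chromosome 17 carried 10.1, against 4.16 over the genome, and chromosome 20 carried 6.67. Chromosomes 13 (1.78) and 14 (1.61) and X (0.859) carried the fewest. The densest 1 Mb windows were at 49000001 to 50000000 on chromosome 5 (62 regions) and 124000001 to 125000000 on chromosome 1 (47 regions), neither with an annotated gene, followed by 143000001 to 144000000 on chromosome 1 (40 regions, protein-coding genes H3-7 and FAM72C), 43000001 to 44000000 on chromosome 17 (38 regions, 20 protein-coding genes with BRCA1, RPL27 and ETV4) and 26000001 to 27000000 on chromosome 19 (37 regions, no annotated gene). Of 23 chromosomes, 21 differed from an even spread by length (two-sided permutation test over 1000 placements, adjusted p from 0.00255 to 0.0175), and chromosomes 11 and 21 did not (adjusted p = 0.123 and 0.769). With a fold enrichment of at least 5, chromosomes 2, 9 and 20 turned from above to below the genome value and still differed, and chromosomes 6, 12 and 16 no longer differed. Of the 822 regions on chromosome 5, 113 lay in 1 stretch without a gene. Without gene-free stretches and mitochondrial pseudogenes, chromosome 5 turned from above to below the genome value and no longer differed. Copy number of the line was not measured, and the assembly's gaps were not removed from the lengths.

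**Figure D3:**
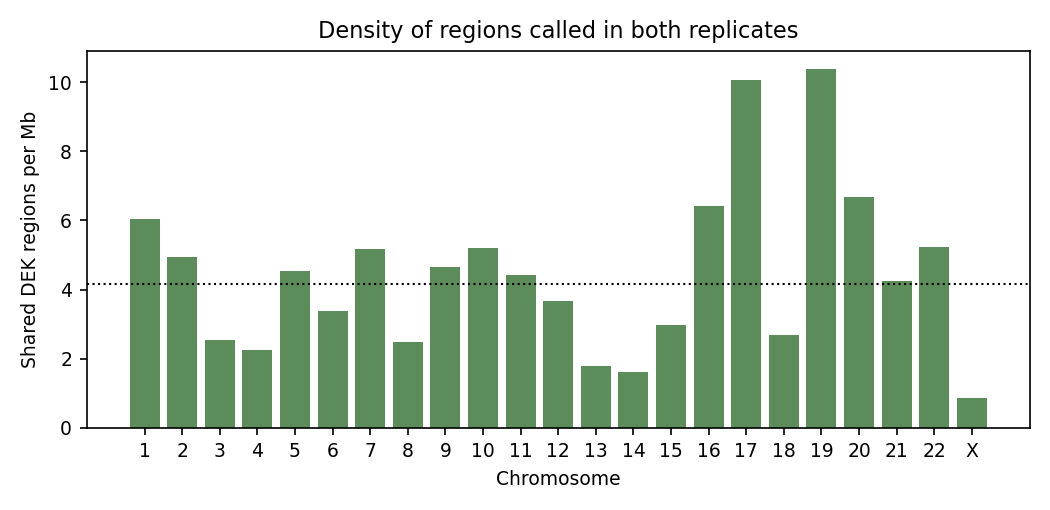
DEK regions called in both replicates per Mb (y axis) on each chromosome (x axis); the dotted line marks the genome value of 4.16 per Mb. Chromosomes 17 and 19 exceed 10 regions per Mb and chromosome X lies at 0.859.

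The 10 strongest shared regions lay outside annotated genes. After the region near MTCYBP13, they were on chromosome 17 at 25920048 to 25920421 (30.3 ± 0.982), chromosome 4 at 51107164 to 51107607 (25.9 ± 2.35), chromosome 21 at 10325598 to 10326001 (25.6 ± 0.15), chromosome 13 at 109424044 to 109424433 (25.5 ± 0.422) and chromosome 3 at 93470290 to 93470851 (24.4 ± 0.667; SD, n = 2 for each). The others were on chromosome 22 at 18730356 to 18730766, chromosome 6 at 61322834 to 61323206 and 58450538 to 58450944, and chromosome 17 at 23016162 to 23016679, with means from 20.9 to 22.5. Of the 109 regions with at least 10-fold enrichment in both replicates, 76 (69.7%) lay in the 30 stretches of at least 1 Mb without an annotated gene, which make up 5.84% of the chromosomes' span, and 0 lay at an end of a protein-coding gene. In those stretches the median fold enrichment was 6.49 and 6.79 in the 2 replicates, against 4.07 and 4.05 elsewhere, while the median reads within 10 kb, averaged over the 2 libraries, were 135 against 261. The stretches held 593 shared regions. Of these, 146 lay on chromosome 1 between 121571889 and 143299517, and 113 on chromosome 5 between 45696381 and 50396191. A stretch on chromosome 19 between 24179012 and 27681071 held 91. Centromeric and other repeat sequence was not set apart, because no genome sequence was used here.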

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

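The tests of explanations in this part were all chosen after the results they bear on had been seen.

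Peaks on the mitochondrial genome lay outside the chromosomes analysed and drew attention because they stood above 0 with no control sample to set them against. Replicate 1 had summit pileups of 323 (the peak of lower coordinate) and 335 (the peak starting at 13438), with fold enrichments of 1.31 and 1.71. Replicate 2 had pileups of 277 (starting at 85) and 293 (starting at 13399), with fold enrichments of 1.92 and 1.70. No explanation was tested for them.

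Of the 109 shared regions with at least 10-fold enrichment in both replicates, 76 lay in stretches without genes. For 8 of the 76, the reads within 10 kb exceeded the median elsewhere by more than counting noise in both libraries. These reads include the peak's own if calling used no control library. The region on chromosome 4 at 51107164 had 386 and 432 such reads, with summit pileups of 216 and 194. The raised reads therefore cannot exclude a background estimated too low in sparsely mapped sequence. It stays a candidate for the other 68, with median reads at most 0.647 times those of 23 equally strong regions elsewhere, likewise without raised reads (Mann-Whitney p = 6.2e-05 and 4.0e-05 in the 2 libraries), although 48 of the 68 lay above the lowest possible background in at least 1 library and the share at it was not past the threshold (20 of 68 against 2 of 23, Fisher's exact p = 0.0517). Many genomic copies piled on 1 assembled copy cannot be told apart from single-copy binding without an input library. The median pileups of the 76 (40 and 47) lay above those of all regions elsewhere (21 and 22). They lay below those of the 33 regions of at least 10-fold elsewhere (75 and 80, a ratio of 0.533 in replicate 1), and strength itself selects for pileup. The design gives no groups to compare, so no biological explanation was tested.

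Shared regions per Mb differed between chromosomes, from 0.859 to 10.4. DNA copy number of the cell line may contribute: over the 23 chromosomes, regions per Mb followed the median reads within 10 kb (Spearman 0.816, permutation p = 1e-05, the smallest possible; Pearson 0.684, p = 0.00037; Pearson 0.624 without chromosomes 20 and X), with a partial Spearman coefficient of 0.801 given gene density (adjusted p = 4e-05 over the 2 relations). Gene density may contribute too, with a Spearman coefficient of 0.693 (permutation p = 0.00036; Pearson 0.815, p = 1e-05; Pearson 0.645 without chromosomes 17 and 19) and a partial coefficient of 0.665 given reads (adjusted p = 0.00019). The reads were counted only around called peaks and, if calling used no control library, include the peaks' own reads, so the first relation is not independent of peak calling. Both explanations stay open, and no biological explanation was tested.

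The 9 gene lists called at gene ends, 8 higher and 1 lower, were set against explanations from the layout of the genome. Within deciles of local region density, 7 of them stayed past the threshold, the olfactory receptors with -4.54 in place of -7.16 points against other genes. Region density within 1 Mb, as measured here, therefore does not account for the whole of these 7. It only stands in for copy number, which was not measured, so a contribution of copy number stays open. Neighbours at 1 region, as in the histone list, still counted separately in this test, which was not combined with counting by nearest gene. The hypoxia and splicing lists no longer passed (exact test, adjusted p = 0.0716 and 0.102). Their differences moved only from 11.9 to 11.3 and from 9.80 to 8.65 points, so regional density cannot be told apart for them. A region counted for several neighbouring genes does not account for the whole of 6, which passed by nearest gene alone although the histone difference fell from 22.98 to 8.33 points, and cannot be told apart for hypoxia, splicing and ribosome biogenesis, whose calls ended (exact test, largest adjusted p = 0.111) with differences still at 10.5, 7.29 and 8.46 points, wide intervals and no region shared by members of the list. Open chromatin recovered by any antibody stays open, because no input or other-antibody library was analysed here. No biological explanation was tested.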

How the results depend on the processing

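Chosen after the data were seen were the tests with local placement, region density strata, whole genes, nearest genes and removal of gene-free stretches, and the other alternatives were fixed before the data were examined. The excess overlap of the replicates (59.2-fold to 472-fold) and the excess of regions at gene ends (2.03-fold to 3.33-fold) kept their direction and side of the threshold wherever they were run. The 21 chromosomes that differed became 18 to 21, as chromosomes 2, 5, 6, 9, 12, 16 or 22 lost the call, and with fold enrichment of at least 5 chromosomes 2, 9 and 20 differed in the other direction. Without gene-free stretches and mitochondrial pseudogenes, chromosome 5 both lost the call and turned its direction. The 12590 shared regions became 4857 with −log10 q of at least 5, 1301 with fold enrichment of at least 5, 2782 with the 5000 peaks of lowest p and 8206 with summits within 100 bp, as fewer peaks or pairs entered. The Spearman coefficient of 0.621 became 0.755, 0.679, 0.828 and 0.656 under the same settings, 0.642 with 50% reciprocal overlap and 0.577 without gene-free stretches and mitochondrial pseudogenes. The 1504 genes with a region at an end became 564, 121, 321 and 994 under the first settings, 2180 to 2703 when either replicate was left out, 2749 with windows of 3 kb and 4388 with whole genes. The 9 lists past the threshold became 3, 0, 0 and 4 under those settings, 4 with 50% reciprocal overlap and 4 with whole genes; 10 passed when either replicate was left out, but not the same ones, since without replicate 1 hypoxia and splicing lost the call and 3 lists gained it, and without replicate 2 oxidative phosphorylation gained it. The percent of list members with a region minus that of other genes changed sign in the cases given here, and the cause was not tested. Stricter settings left fewer genes with a region at an end. With −log10 q of at least 5 it was -2.83 for hypoxia and G1/S genes, none of whose members had a region, 3.06 for VHL-HIF components, -0.324 for immediate-early genes and 0.749 for immune markers. With fold enrichment of at least 5 it was 5.28 for VHL-HIF components, -0.607 for the hypoxia, ribosome biogenesis, G1/S, G2/M, NF-kB, immediate-early, heat shock, ATF4 and renal tubule lists and -0.608 for histone, ribosomal protein and oxidative phosphorylation genes, none of whose members had a region. With the 5000 peaks of lowest p it was -1.61 for hypoxia and G1/S genes, again with no member left, 4.28 for VHL-HIF components and 1.97 for immune markers. With 50% reciprocal overlap it was 0.185 for VHL-HIF components, -0.699 for immediate-early and -0.142 for mesenchymal genes. With summits within 100 bp it was 0.907 for VHL-HIF components, 0.0236 for repair genes, -1.85 for the NF-kB list, -2.20 for mesenchymal genes and 0.135 for ZNF genes. When either replicate was left out it ran from 4.09 to 8.99 for repair genes, 0.197 to 0.357 for interferon-stimulated genes and 0.0901 to 2.44 for ZNF genes. For the NF-kB list it was -1.03 without replicate 1, while without replicate 2 it kept its sign (7.85). With windows of 3 kb it was 9.77 for VHL-HIF components and 6.76 for HOX genes. Within density strata it was 0.394 for repair genes and 1.15 for neuron markers, and with nearest genes 1.22 for neuron markers. With whole genes it was 19.2 for VHL-HIF components, -5.31 for histone chaperones, -7.18 for ribosomal proteins, -2.46 for ribosome biogenesis, -6.43 for G1/S, -3.46 for G2/M, -8.53 for splicing, -6.35 for the NF-kB list and -7.13 for oxidative phosphorylation. The whole-gene setting did not adjust for gene length. Over all alternatives, the reported list results kept direction and side of the threshold in 235 cases and changed sign in 51; the 9 called lists lost the call in 54 of 125 cases, some of them with a change of sign, and other lists gained it in 7. Of the 83 genes that the rule for named genes gave with a region at an end, 28 had no region at an end with −log10 q of at least 5, 54 with fold enrichment of at least 5 and 26 with summits within 100 bp. With 50% reciprocal overlap and summits within 100 bp the overlap test used 100 placements (permutation p = 0.0198, the smallest they can give). Alternatives fixed in advance that needed a genome sequence, strand or transcripts were not run: motif windows, GC and CpG content, CpG strata, repeat-masked sequence, GC-matched placement, the asymmetric promoter window and every annotated start site. No paired analysis was possible because the labels give 1 group of 2 replicates. The median pileup of 19 limits all of these results at the level of single peaks.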

Other observations

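The test of mitochondrial pseudogenes and the choice of genes with many regions in this part were made after the data were seen.

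Shared DEK regions clustered inside some protein-coding genes, and 223 genes held at least 5 summits, against a genome average of 0.416 regions per 100 kb. CMIP on chromosome 16 held 19 regions (7.12 per 100 kb), SEPTIN9 on chromosome 17 held 15 (6.85), SHB on chromosome 9 held 12 (7.83), COL18A1 on chromosome 21 held 10 (9.21) and RXRA, which encodes a nuclear receptor, held 10 (8.76). Per length the densest among these 223 were STRA6 (15.2 per 100 kb), HMOX2 (14.04), HOXA3 (13.2), TCF7 (12.5) and HAVCR1 (12.5), the last a kidney injury marker. These genes were named after their values were seen, and genes in amplified or gene-rich sequence were not set apart.

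Of 479 mitochondrial pseudogenes in the nuclear genome, 11 (2.30%) held a shared region, against 173 of 16185 other pseudogenes (1.07%; Fisher's exact p = 0.0221, not adjusted). The 11 rested on 9 distinct regions and the 173 on 164, and with each region counted once the difference was not past the threshold (Fisher's exact p = 0.1007, not adjusted). The group on chromosome 1 with MTND1P23, MTCO1P12 and MTATP6P1 had up to 3031 reads within 10 kb of a summit in replicate 1 and 2719 in replicate 2. MTRNR2L8 on chromosome 11 had fold enrichments of 11.3 and 12.1, and MTRNR2L12 on chromosome 3 had 10.9 and 7.12. Reads of mitochondrial DNA and of these copies were not separated here.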
